A study of Homo sapiens with 6 samples.

How the data were processed

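RNA was measured by 3SEQ in 6 formalin-fixed, paraffin-embedded UPS, with 1 library per tumour. Per the labels' protocols, tissue cores of 2 mm were taken, polyadenylated RNA was selected with oligo(dT) and sheared by heat to fragments of 100 to 200 nucleotides, and the first 36 bases of each fragment were sequenced. Reads were placed on genome build hg19, per the submitters' processing notes. The aligner, the counting tool and the gene annotation are not given in the sources used here, nor is whether counting used the strand.

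The deposited values are RPM, the reads of a gene per megaread: each column of the authors' table sums to the same round total, and every value is a whole multiple of 1 step per column. They are not divided by gene length, although the deposited table carries the name TPM. With a tolerance of 0.01 reads, 132864 of 132864 values (100%) came out as whole reads, which gave the library totals. Reads of formalin-fixed RNA that share a gene copy, or of overlapping and antisense genes, cannot be told apart in these values.

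The table lists 22144 genes. The 102 genes that are Y-linked or are XIST or TSIX were left out when the table was read, and 22042 genes were used, of which 18706 had at least 1 read. Of these symbols, 18273 matched a current symbol of the GENCODE-based gene table, 2468 an older symbol through RefSeq synonyms (assembly GRCh38.p14) and 1301 neither. Those tables and GENCODE v29 transcripts served only for names, gene order and the GC content of the last 500 bases of each gene's longest transcript; no coordinates are given, because the builds differ.

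The tumours formed 1 group, so no groups were compared. Values were analysed as log2(RPM + 1). A list score is the mean of this value over the members found. The 34 lists, fixed with the tests before the data were examined, covered lineages, cell types, immune function, cellular processes, cancer pathways and reference sets. Each list was compared with the smooth muscle list in the same tumours by an exact sign-flip permutation test, two-sided, with 64 sign patterns. The level of a list was its median's percentile among 10000 random lists of the same size. Variable genes were those with a mean of at least 10 RPM and an SD in the top 5% of 20 bins of similar mean, and lists were tested for over-representation with Fisher's exact test among the 6230 genes above the filter. Coherence was the mean pairwise Pearson correlation between members, against 10000 random lists matched on mean level. Correlations between 6 scores used all 720 orderings. Lists needed 3 members above the filter, and p-values were adjusted by Benjamini-Hochberg within each family.

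The text names the 3 most abundant members and the most variable member of each list, the 15 most abundant genes, the 25 genes with the largest SD among those with a mean of at least 50 RPM, and 26 genes fixed in advance. CKM, COL1A2, COL3A1, B2M, EEF1A1, IBSP, PHOSPHO1, PTH1R, RUNX2, FABP4, MYOD1, MYH3, CDH15, MET, CALR, FARSA, GCDH and GADD45GIP1 were named after their values were seen, as were APOB, ALB and FABP1, used as markers of gut and liver.

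The recovered reads also went into a chi-square test of equal shares (genes with at least 5 expected reads in each library) and into edgeR, whose tagwise dispersion replaced the SD as an added alternative. By that measure 320 genes were called, 288 of them shared with the main measure, at a common biological coefficient of variation of 0.665. Alternatives varied the pseudocount (10), the scaling (upper quartile), the filter (1 or 50 RPM), the list summary, the share of genes called, the correlation coefficient and the tumours included.

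The recovery of reads, the variable genes, coherence and list level were tested on simulated reads drawn from the real means and library sizes. Simulated genes given no added SD or shared pattern varied independently of each other, all by the same log2 SD. The chi-square test, the edgeR dispersions and the ratio used later to single out values were not simulated. All simulated values were recovered as the reads drawn. For variable genes, over 5894 genes, 41.0% of 61 genes with an added SD of 1, 77.8% of 63 with an added SD of 2 and 92.4% of 66 with an added SD of 3 were called, against 2.89% of the others. For coherence, 19 of 20 coherent lists and 0 of 60 null lists were called. The null lists held independent genes, so the 0 of 60 gives no rate of false calls where genes vary together. For list level, 4 of 60 null lists fell outside the middle 95%. The sign-flip and correlation tests were tried on normally distributed random numbers instead, at an unadjusted threshold of 0.05. The sign-flip test called 3.05% of null differences and 87.6% of differences of 2 SD. The correlation test called 4.65% of null pairs and 79.6% of pairs with a true r of 0.9. These rates do not carry over to the adjusted p-values by which the results were judged. Random gene sets passed the later tests of GC content and of neighbouring genes in 2 and 1 of 40 draws.

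Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.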

Results

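The study profiled undifferentiated pleomorphic sarcoma (UPS), a soft tissue sarcoma with no recognisable line of differentiation, and leiomyosarcoma, a malignant tumour of smooth muscle differentiation, by 3SEQ, which sequences the 3′ ends of polyadenylated RNA. It asked how the expression of UPS differs from that of leiomyosarcoma and its subtypes. Only the 6 UPS are covered here, named UPS 1 to UPS 6; the leiomyosarcomas are not analysed here. All 6 formed 1 group, so the values describe levels within these tumours and differences from tumour to tumour. The libraries held 4348579 reads in UPS 1, 4441428 in UPS 2, 4453786 in UPS 3, 6659029 in UPS 4, 5116566 in UPS 5 and 6599021 in UPS 6. A gene with no read in a library could therefore have been present at up to 0.690 RPM (reads of a gene per megaread of its library) in the shallowest library and up to 0.451 RPM in the deepest, at 3 reads. These floors cover counting error only, since the reads carried no molecular identifiers. The labels list the tumours as separate samples, and every SD given below measures the variation between these 6 samples. Of the tests, the sign-flip and score correlation tests use the tumours as units. Those of over-representation, coherence and neighbouring genes set genes against other genes instead. The chi-square test sets differences between tumours against counting noise alone.

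The most abundant transcripts included those of the cytoskeleton, glycolysis and the ribosome. ACTB, which encodes beta-actin, averaged 32247 RPM and the glycolytic enzyme gene GAPDH averaged 17496 RPM. RNF168, a ubiquitin ligase gene of the DNA damage response, stood second at 28124 ± 14154 RPM (SD, n = 6). Whether these reads came from RNF168 itself was not tested, since the values hold no read positions. The short non-coding BCYRN1 ranged from 695.1 RPM in UPS 3 to 43702 RPM in UPS 6, and the ribosomal RNA gene RN5-8S1 averaged 7744 RPM. Genes of ribosomal proteins took 7.16% of the reads in UPS 2 and 7.74% in UPS 5, against 12.8% to 18.1% in the other 4 tumours. The 10 most abundant genes took 14.2% to 20.8% of each library. Between 5454 and 6444 genes reached 10 RPM in a tumour, with a median of 5727.5, and between 11393 and 12759 reached 1 RPM.

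By Spearman's rho the tumours resembled each other to a similar degree and no library repeated another. Spearman's rho over the 6230 genes with a mean of at least 10 RPM had a median of 0.766 over the 15 pairs of tumours, with a range of 0.710 to 0.837. This correlation is across genes, which are not independent replicates. In a chi-square test of the recovered reads, the differences within pairs came to 104.2 to 179.5 per gene, where counting noise alone gives about 1. Of 12346 genes with enough reads, 10969 (88.8%) differed between the 6 tumours by more than counting noise after Benjamini-Hochberg adjustment. Both uses of the test take reads as independent, although they carried no molecular identifiers, so the values may be too high. Principal component 1 held 29.4% of the variance and mainly set UPS 3 (weight 0.53) and UPS 6 (0.58) against UPS 5 (−0.50). Component 2 held 26.4% and mainly set UPS 2 (0.87) apart.

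The first comparison set each gene group against the smooth muscle contractile list in the same tumours, the list that stands for the differentiation of leiomyosarcoma. Smooth muscle genes were present at uneven levels. MYL9, the regulatory light chain of smooth muscle myosin, averaged 1520 ± 1169 RPM and tropomyosin TPM2 averaged 1929 ± 1337 RPM (SD, n = 6). PDLIM7, which encodes a cytoskeletal LIM protein, averaged 439.4 ± 207.7 RPM. Several markers used to diagnose smooth muscle tumours were far lower. ACTA2, smooth muscle actin, averaged 5.03 ± 4.86 RPM, CNN1 (calponin) 26.1 ± 43.6 RPM, MYH11 (smooth muscle myosin heavy chain) 19.1 ± 25.2 RPM and CALD1 (caldesmon) 19.2 ± 6.11 RPM. LMOD1, which encodes leiomodin, averaged 2.09 ± 2.76 RPM. MYOCD, the transcriptional coactivator that drives the smooth muscle programme, averaged 0.208 ± 0.203 RPM and lay below the floor of 3 reads in UPS 1, UPS 2, UPS 3, UPS 5 and UPS 6. The intermediate filament gene DES was at 1369 RPM in UPS 5 and 275.7 RPM in UPS 4, against 0.920 to 8.64 RPM in the other 4 tumours. The smooth muscle score, the mean of log2(RPM + 1) over the list, was 4.08 ± 0.70 (SD, n = 6). It was lowest in UPS 3 at 3.24 and highest in UPS 5 at 5.17, where the skeletal muscle score was also highest; DES, which striated muscle expresses too, followed the order of the skeletal muscle genes. The median of its 20 members lay at percentile 97.4 among 10000 random lists of detected genes, just inside the middle 95%. By the same measure 9 lists lay above the middle 95%: matrix, macrophage, HLA class I, HLA class II, endothelial, matrix remodelling, mitochondrial respiration, ribosomal protein and housekeeping genes. Liver or gut, cancer-testis and Schwann cell and melanocyte genes lay below it, at percentiles 0.07, 1.12 and 1.92, but none of the 3 did against random lists from all genes. Against random genes of the same GC content, an alternative chosen after seeing the data, smooth muscle lay at percentile 89.3. The 9 high lists stayed high there, joined by proliferation (99.6), TGF-beta and YAP target (99.9) and immediate early genes (98.5).

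In all, 6 gene groups scored higher than smooth muscle in all 6 tumours, namely matrix, macrophage, HLA class I, matrix remodelling, ribosomal protein and housekeeping genes. With only members of at least 10 RPM, 2 lists were higher and 6 lower in every tumour, against 6 and 12 with all members. The collagen and fibroblast matrix score lay 1.97 ± 0.71 (SD, n = 6) above that of smooth muscle on the log2 scale. Its leading members were COL6A2 at 6304 ± 4970 RPM, COL1A1 at 5366 ± 5969 RPM and the proteoglycan gene BGN at 1646 ± 807.2 RPM. Macrophage genes scored 1.76 ± 0.81 higher than smooth muscle. The complement genes C1QB and C1QA averaged 2488 ± 1558 RPM and 2067 ± 1162 RPM, and the signalling adaptor TYROBP averaged 1134 ± 557.7 RPM. CSF1R, the receptor of macrophage colony-stimulating factor, averaged 513.6 ± 216.5 RPM, CD68 294.3 ± 103.8 RPM, the scavenger receptor CD163 5.43 ± 2.70 RPM and the ligand gene CSF1 8.18 ± 9.91 RPM. HLA class I genes scored 2.18 ± 0.61 higher. Genes of this class have near-identical copies, so reads may be split between them. Matrix remodelling genes scored 0.96 ± 0.76 higher, led by the protease inhibitor gene TIMP1 at 3891 ± 4017 RPM and the gelatinase gene MMP2 at 1818 ± 1090 RPM. The ribosomal protein list lay 6.06 ± 1.13 above and the housekeeping list 2.64 ± 0.75 above.

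Another 12 groups scored lower than smooth muscle in all 6 tumours. The largest differences were those of steroid hormone receptors (−3.44 ± 0.83), cancer-testis antigens (−3.35 ± 0.62), neural genes (−3.16 ± 1.01), liver or gut genes (−3.11 ± 0.71) and Schwann cell and melanocyte genes (−2.72 ± 1.01; SD, n = 6 for each). The oestrogen receptor gene ESR1 averaged 0.339 ± 0.443 RPM and the progesterone receptor gene PGR 0.465 ± 0.497 RPM, and both were below the floor of 3 reads in 4 of 6 tumours. S100B, a Schwann cell and melanocyte marker, averaged 5.58 ± 3.61 RPM. Epithelial genes (−2.18 ± 0.82), B and plasma cell genes (−2.14 ± 0.71), histones (−2.04 ± 1.02), T and NK cell genes (−1.75 ± 0.51), adipocyte genes (−1.69 ± 0.96), immune checkpoint genes (−1.36 ± 0.58) and neutrophil and mast cell genes (−1.22 ± 0.66) were also lower. The histones are replication histones, whose messages mostly lack a poly(A) tail. After selection with oligo(dT), their score cannot be read as low expression. The T cell receptor subunit gene CD3E averaged 21.6 ± 14.5 RPM and the cytotoxic granule gene NKG7 66.2 ± 50.2 RPM. CD274, which encodes the checkpoint ligand PD-L1, averaged 0.128 ± 0.160 RPM, with each tumour below its floor of 3 reads, while the related CD276 averaged 119.4 ± 63.1 RPM.

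The other 15 groups did not differ from smooth muscle in the same direction in all tumours. Skeletal muscle genes lay −1.33 ± 1.73 from smooth muscle and were higher in 1 of 6 tumours, and cartilage and bone genes lay −1.44 ± 0.93 from it. Endothelial genes differed by 0.75 ± 0.86, HLA class II by 1.05 ± 0.65, mitochondrial respiration by 0.91 ± 0.71 and erythroid genes by −1.01 ± 1.07. Differences were −0.26 ± 0.91 for interferon response, −0.53 ± 0.96 for proliferation, −0.07 ± 0.54 for hypoxia and glycolysis, −0.03 ± 0.54 for TGF-beta and YAP targets and −0.22 ± 0.86 for immediate early genes. They were −0.98 ± 0.83 for p53 pathway genes, −1.25 ± 0.99 for genes of the long arm of chromosome 12, −0.33 ± 0.70 for cell cycle control and −0.996 ± 0.894 for growth factor receptors (SD, n = 6 for each). In this last set of groups, FGFR1 averaged 77.7 ± 36.3 RPM, AXL 552.2 ± 274.9 RPM, MDM4 101.9 ± 27.1 RPM and CCND1, the gene of cyclin D1, 234.7 ± 136.7 RPM. MDM2 and CDK4, the 12q genes amplified in dedifferentiated liposarcoma, averaged 4.316 ± 2.501 RPM and 6.63 ± 2.29 RPM, with no tumour above 8.79 RPM and 10.5 RPM. HMGA2 averaged 4.13 ± 2.81 RPM. The tumour suppressor gene RB1 averaged 1.69 ± 1.18 RPM.

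**Figure D1:**
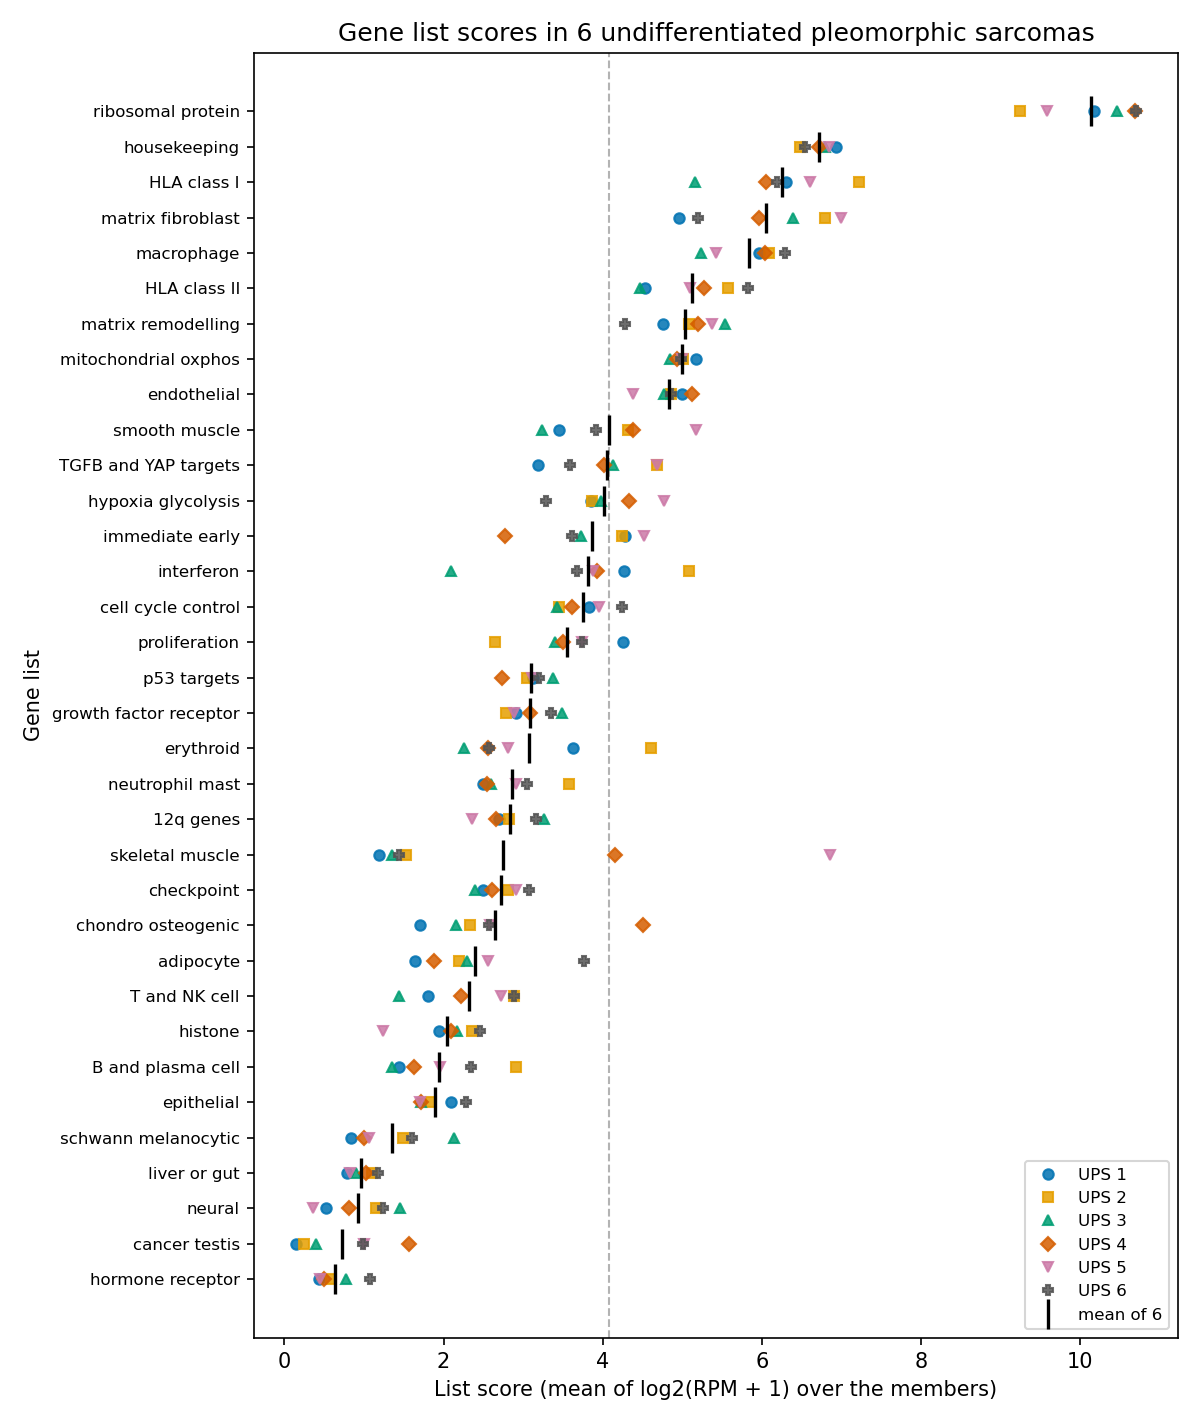
Scores of the 34 gene lists, as the mean of log2(RPM + 1) over the members (horizontal axis), in each of the 6 tumours (symbols), with the mean of 6 as a black bar and the mean of smooth muscle as a dashed line. Skeletal muscle spreads from 1.19 to 6.85, while mitochondrial respiration stays between 4.85 and 5.17.

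The differences were tested with an exact sign-flip permutation test, two-sided, over the 6 tumours, with 33 lists in the family. The 18 lists that lay on one side in all 6 tumours had p = 0.0312, the smallest the exact test of 6 values can give, and an adjusted p of 0.0573, so 0 of 33 lists passed the adjusted threshold of 0.05 and 18 passed it unadjusted. With 33 lists, 21 would have to reach the smallest p of the exact permutation test for any to pass. The values of abundant transcripts went with the GC content of their 3′ ends (rho = 0.43 across the 400 list members with a GC value). Relative to genes of the same GC content, an alternative chosen after seeing the data, 22 of the 33 lists passed, each with an adjusted p of 0.0469 in the exact permutation test. The mean difference changed sign for 7 lists: to 0.65 for hypoxia and glycolysis and 1.24 for TGF-beta and YAP targets, both among the 22, and to 0.65 for immediate early genes, 0.36 for interferon response, 0.32 for proliferation, 0.32 for cell cycle control and 0.08 for growth factor receptors, which did not pass. The directions of these groups relative to smooth muscle are therefore not settled. The order of the lower groups shifted too. Steroid hormone receptors then lay at −2.28 and Schwann cell and melanocyte genes at −1.78, with cancer-testis antigens lowest at −2.75.

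Beyond the levels, 13 of the 14 skeletal muscle genes with a mean of at least 10 RPM were among the genes that varied most from tumour to tumour. In UPS 5 the troponin genes TNNC2, TNNT3 and TNNI2 were at 3332, 2670 and 2111 RPM, and the oxygen-binding myoglobin gene MB at 1554 RPM. In UPS 4 the same genes were at 74.2, 210.1, 95.1 and 292.8 RPM. In the other 4 tumours MB did not exceed 1.06 RPM and TNNC2 did not exceed 5.29 RPM, while TNNT3 reached 95.9 RPM in UPS 2. TNNI1, COX6A2 and MYBPC2, further genes of striated muscle, were at 507.0, 331.5 and 674.5 RPM in UPS 5 and at 180.7, 38.6 and 36.2 RPM in UPS 4. The skeletal muscle score was 6.85 in UPS 5, 4.16 in UPS 4 and 1.19 to 1.53 in the rest. The smooth muscle list had 3 of 11 members among the variable genes, which did not pass (adjusted p = 0.0912, Fisher's exact test).

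Erythroid genes and cartilage and bone genes were over-represented as well. HBA2 and HBA1, the alpha-globin genes, reached 2458 and 999.7 RPM in UPS 2, and HBA2 lay between 28.1 and 298.0 RPM elsewhere. The globin pair is near-identical, so reads may be split between the copies. COMP, a cartilage matrix gene, was at 2137 RPM in UPS 2, 634.8 in UPS 4 and 605.1 in UPS 5 and did not exceed 13.02 RPM in the other 3 tumours. SP7, the osteoblast transcription factor osterix, was at 235.8 RPM and ALPL, the phosphatase of mineralising bone, at 358.8 RPM in UPS 4. COL1A1, of the matrix list, ranged from 240.2 RPM in UPS 6 to 14622 RPM in UPS 5.

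**Figure D2:**
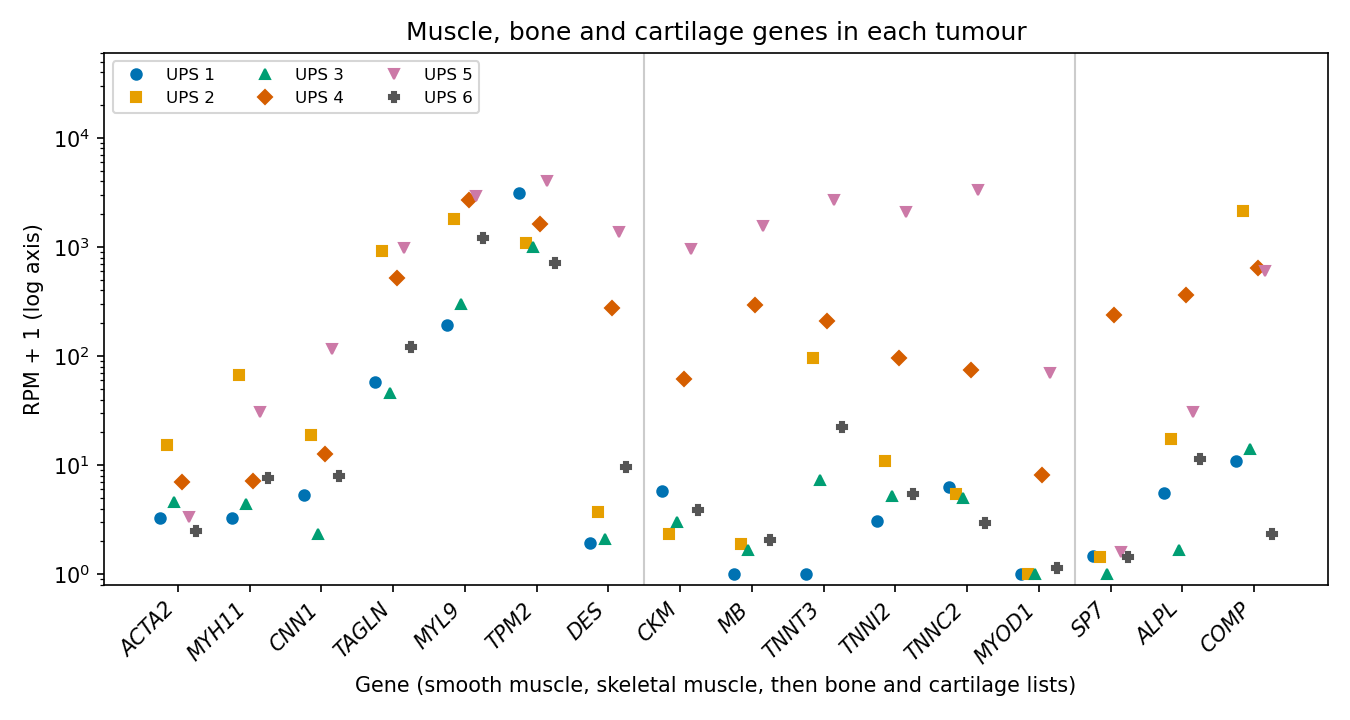
RPM + 1 on a log axis for genes of the smooth muscle list (ACTA2 to DES), the skeletal muscle list (CKM to MYOD1) and the cartilage and bone list (SP7 to COMP), with 1 symbol per tumour. The skeletal muscle genes shown are highest in UPS 5 and next in UPS 4, and SP7 stands at 235.8 RPM in UPS 4 alone.

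Variable genes were the 320 of 6230 with a between-tumour SD of log2(RPM + 1) in the top 5% of genes of similar mean. Over-representation by Fisher's exact test, one-sided, passed for 3 of 28 lists: skeletal muscle (adjusted p = 5.12e-15, 13 of 14 members), erythroid (adjusted p = 0.00723, 3 of 4 members) and cartilage and bone (adjusted p = 0.0223, 3 of 6 members). Members of a list are not independent, so these p-values describe the lists in these 6 tumours. Without UPS 4 the cartilage and bone list no longer passed (2 members, adjusted p = 0.108), and without UPS 2 neither did the erythroid list (2 members, adjusted p = 0.0677, Fisher's exact test). Without UPS 5 the skeletal muscle list passed with 5 variable members.

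Members of 13 of 28 lists moved together from tumour to tumour more than random genes of similar level. Skeletal muscle genes had the highest mean pairwise correlation at 0.92, followed by T and NK cell genes at 0.75, HLA class I at 0.73, interferon response genes at 0.70 and ribosomal protein genes at 0.67. In the interferon group, IFI27 was at 20.4 RPM in UPS 3 and at 536.0 to 4454 RPM elsewhere, ISG15 at 159.4 RPM in UPS 3 and at 302.0 to 1962 RPM elsewhere, and the interferon score was 2.09 in UPS 3 against 3.67 to 5.08 in the other 5 tumours. UPS 2 had the highest HLA class I score at 7.22 and UPS 3 the lowest at 5.16. HLA class II genes had a mean correlation of 0.56, proliferation genes 0.55, macrophage genes 0.38, TGF-beta and YAP targets 0.37, hypoxia and glycolysis genes 0.35, immediate early genes 0.33, matrix genes 0.32 and smooth muscle genes 0.29. With each tumour left out in turn, the value was 0.40 to 0.82 for interferon response, 0.34 to 0.60 for HLA class II and 0.28 to 0.72 for proliferation genes. MKI67, the proliferation marker Ki-67, ranged from 39.9 RPM in UPS 2 to 200.3 RPM in UPS 5, and the proliferation score from 2.65 in UPS 2 to 4.26 in UPS 1. Genes of endothelium, housekeeping functions, mitochondrial respiration and the p53 pathway had mean correlations of 0.13, 0.07, 0.09 and 0.06 and did not pass.

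**Figure D3:**
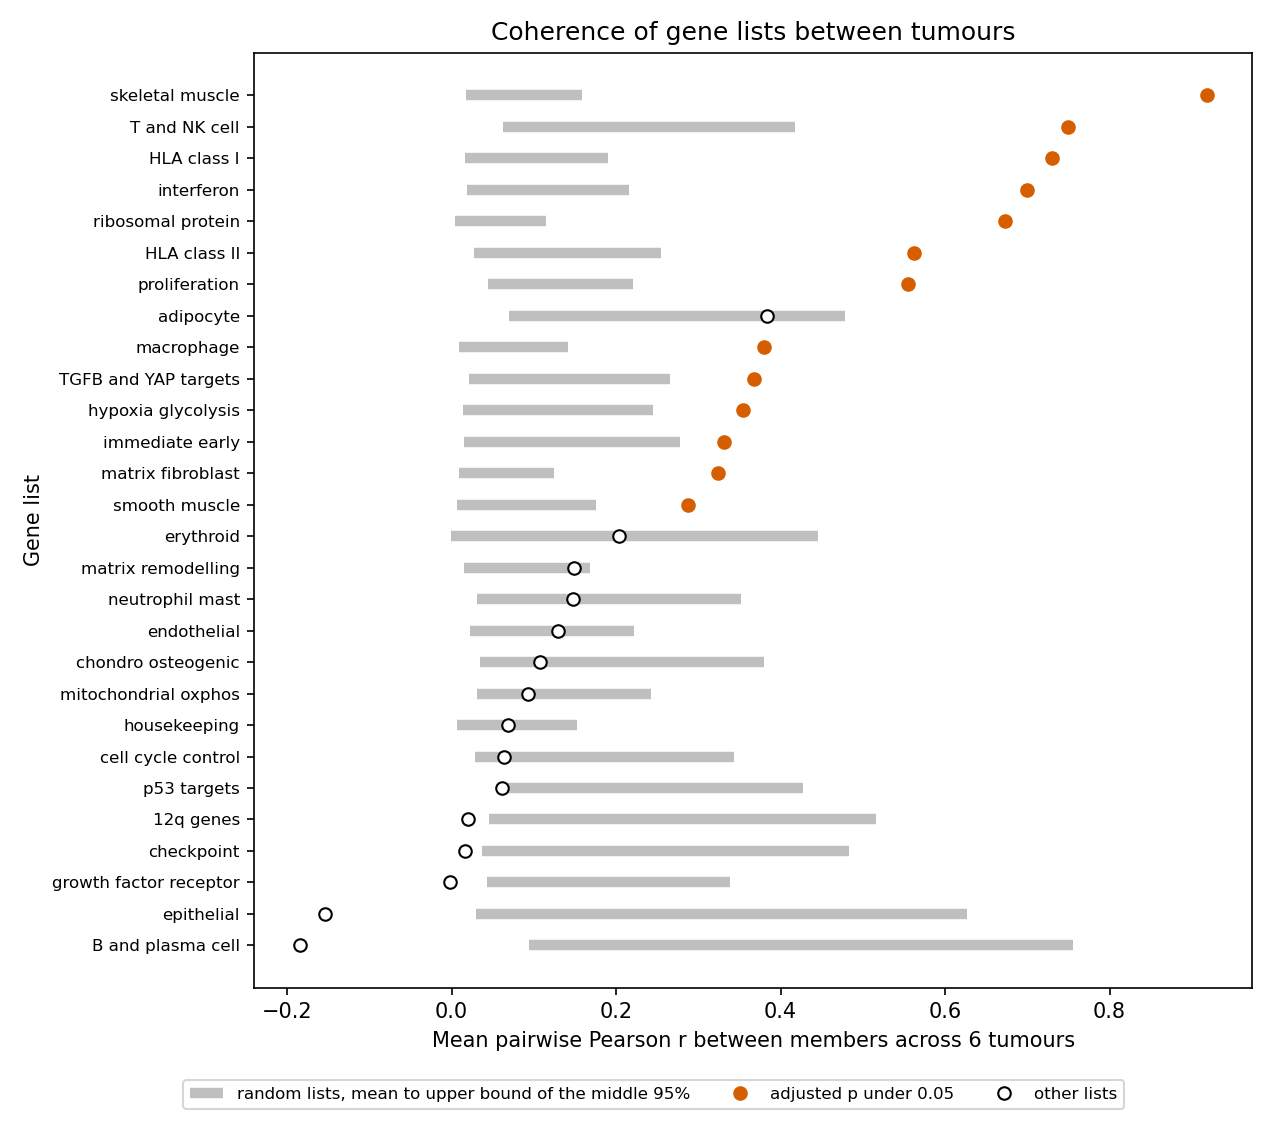
Mean pairwise Pearson correlation of log2(RPM + 1) between members of each list across the 6 tumours (points) and the range from the mean to the upper bound of the middle 95% of 10000 random lists of similar level (grey bars). The 13 filled points passed the adjusted threshold, from 0.29 for smooth muscle to 0.92 for skeletal muscle.

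The test was a one-sided permutation against 10000 random lists, Benjamini-Hochberg adjusted over the 28 lists. The smallest p that it can give, 0.0001, was reached by 6 lists (adjusted p = 0.000467). The skeletal muscle result rested on UPS 4 and UPS 5: with both left out, a choice made from their muscle values, its mean correlation was −0.116 and 8 lists passed. The smooth muscle result (adjusted p = 0.00644) rested on UPS 5, without which the mean correlation was 0.04 and did not pass (adjusted p = 0.406 by permutation); immediate early genes fell below the threshold without UPS 4 (0.04), hypoxia genes without UPS 6 (0.20) and TGF-beta and YAP targets without UPS 5 (0.31) or UPS 6 (0.21).

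None of the 15 correlations between the scores of smooth muscle, matrix, macrophage, T and NK cell, proliferation and hypoxia genes held up. The largest was between smooth muscle and T and NK cell scores, with Pearson's r = 0.71 (exact permutation p = 0.125, adjusted p = 0.497) and Spearman's rho = 0.49 (exact permutation p = 0.356). Without UPS 3 and UPS 5, the 2 tumours farthest from the median smooth muscle score, r was 0.54. Matrix and proliferation scores gave r = −0.67 (exact permutation p = 0.138, adjusted p = 0.497) and rho = −0.66 (exact permutation p = 0.175), and r = −0.15 without UPS 1 and UPS 6. Macrophage and T and NK cell scores gave r = 0.54 (exact permutation p = 0.265) and rho = 0.83 (exact permutation p = 0.0583), and r = 0.80 without UPS 3 and UPS 5. Over the family of 15 pairs, 0 passed by either coefficient after adjustment and 0 had an unadjusted p under 0.05 in the exact permutation test.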

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

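The tests of gut and liver transcripts, and the genes added to those chosen in advance, were chosen after the results were seen. A value was singled out where the highest or lowest of the 6 tumours stood apart from the rest by Dixon's ratio on the log2 scale. Of 218 sets of values examined, 31 were singled out. Chance gives about 1 in 20, but only for sets chosen without regard to their values. Many of the genes singled out, such as APOA4, IFITM5 and SAA1, were named for their large SD between these same tumours. The most variable member of each list was picked from these values too, and the genes added later were chosen because they stood apart. The 31 therefore cannot be compared with the chance rate.

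The cartilage and bone list scored 4.50 in UPS 4, against 1.70 to 2.59 in the other tumours. With it stood IFITM5, an osteoblast membrane protein gene, at 1928 RPM, SP7 at 235.8 RPM, the bone sialoprotein gene IBSP at 46.1 RPM, the mineralisation phosphatase gene PHOSPHO1 at 119.4 RPM and the parathyroid hormone receptor gene PTH1R at 335.9 RPM, with other tumours at 13.6 RPM or less for each. These genes are named because they peaked in UPS 4; the list as a whole did not cohere (mean r 0.11, adjusted p = 0.338 by permutation), and other members peaked elsewhere, such as COMP in UPS 2. CCND3, which encodes cyclin D3, was at 1349 RPM in UPS 4 and at 130.4 to 266.3 RPM in the rest.

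In UPS 3, the cystatin gene CST1 was at 1873 RPM against 8.56 RPM or less elsewhere, the protease gene CTSB at 791.7 RPM and the stress response gene IER3 at 1842 RPM, while CD68 was lowest at 118.6 RPM. SAA1, an acute phase protein gene, was at 909.8 RPM in UPS 5 against 3.91 RPM or less elsewhere. In UPS 6, FABP4, a fatty acid carrier gene of adipocytes, was at 59.7 RPM against 1.37 RPM or less elsewhere, and the mesenchymal filament gene VIM was lowest at 28.5 RPM. In UPS 1, the mitotic regulator gene FOXM1 was at 2909 RPM and IER2 at 422.0 RPM.

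UPS 2 held most genes that were high in 1 tumour alone. APOA4, an apolipoprotein of the gut, was at 5335 RPM, BAI1 at 2121 RPM, the water channel gene AQP5 at 1414 RPM, the dopamine transporter gene SLC6A3 at 953.7 RPM, SLC6A13 at 793.2 RPM, the mucin gene MUC4 at 726.1 RPM and ACTRT2 at 721.2 RPM, each at 2.73 RPM or less in the other tumours. CLDN5 at 1022 RPM, HLA-E at 1027 RPM and the lysosomal protease gene CTSD at 40729 RPM were also highest in UPS 2. In UPS 1, genes that lie side by side were high together: CALR at 21835 RPM, GADD45GIP1 at 9947 RPM, FARSA at 6988 RPM and GCDH at 1415 RPM, against at most 2546, 511.1, 459.2 and 71.7 RPM elsewhere. The receptor gene MET was at 189.7 RPM in UPS 1 and at 0.977 RPM or less elsewhere.

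Among the 6230 genes with a mean of at least 10 RPM, 84 exceeded the next tumour at least 16-fold in RPM + 1, 46 of them in UPS 2, where gut or liver tissue is argued against by APOA1, which has a GC-rich end (66.2%) and stood at 6.98 RPM beside 5335 RPM of APOA4; ALB, APOB and FABP1 had 0 reads there, but their ends are AT-rich (36.8% to 37.8% GC), so they add little, and some other genes typical of liver are among the 46. Pooled over tumours, the genes were GC-rich at their ends, with a median of 56.2% against 51.0% in random genes of the same level, at percentile 100, and at percentile 98.2 without UPS 2; of the 3 tumours with 10 or more such genes, only UPS 2 passed singly (percentile 99.9), not UPS 5 (56.7%, percentile 97.3) or UPS 4 (50.5%, percentile 62.0). Their neighbours in gene order, genes of the same name family left out, were higher in the same tumour by 0.44 on the log2 scale against 0.01 in random genes, at percentile 100 with and without UPS 2 (permutation p = 0.0001, the smallest it can give). Taken singly, only UPS 1 (2.06) and UPS 2 (0.53) passed the bound set beforehand, and UPS 3 (−0.09), UPS 4 (0.15), UPS 5 (0.14) and UPS 6 (0.47) did not. The UPS 1 value rests on 4 genes. Among them GCDH and GADD45GIP1 share the neighbours FARSA and CALR, so they are not independent of each other. In UPS 2 some genes of the set likewise shared neighbours or were neighbours of each other, so its value does not rest on independent stretches either. A bias towards GC-rich fragments in single libraries or a cause that acts on stretches of neighbouring genes may each account for part of the set and stay open, and no biological explanation by sample group was tested, because the labels give 1 group.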

How the results depend on the processing

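Alternatives by GC content, edgeR dispersion, thinned reads, close copies left out, and UPS 4 and UPS 5 both left out were chosen after seeing the data. No list passed against smooth muscle under any alternative fixed beforehand. The 0 with each tumour left out says nothing on stability, since the smallest p of the exact permutation test of 5 tumours is 0.0625. With only members of at least 10 RPM, 2 lists were higher and 6 lower than smooth muscle in every tumour, where fewer members remain; relative to genes of the same GC content, 22 lists passed and 10 were higher in every tumour. Leaving out each tumour in turn gave 6 to 9 higher and 12 to 15 lower lists, the highest counts without UPS 5 and UPS 3, and 9 to 10 lists at a high level. Against random lists from all genes, liver or gut, cancer-testis and Schwann cell and melanocyte genes were no longer low (percentiles 2.68, 10.7 and 12.6). Against random genes of the same GC content, proliferation, TGF-beta and YAP target and immediate early genes were at a high level as well. Over-represented lists numbered 6 with upper quartile rescaling and 6 with the top 10% of each bin, and 3 to 4 with a tumour left out; the cause of the first was not tested, and the second calls more genes. Coherent lists numbered 8 with UPS 4 and UPS 5 both left out, where 4 tumours remain, and 11 to 14 with each left out; there the mean correlation turned to −0.0607 for smooth muscle and −0.116 for skeletal muscle, so both rested on these tumours, which were picked for their muscle values. No score correlation passed under any alternative. The 0 with each tumour left out says little, since 6 of 15 pairs would have to reach the smallest p of the exact permutation test of 5 tumours, 0.0167. The median rho between tumours was 0.910 with no filter, because genes low in all tumours enter, and 0.736 to 0.765 with a tumour left out. Rescaling moved the median gene by −0.29 (UPS 6) to 0.16 (UPS 5) on the log2 scale. Of the other alternatives of these counts, 79 equalled the main value or stayed within 1.5 times of it. The depth of 4348579 to 6659029 reads leaves genes such as MYOCD, ESR1, PGR and CD274 at or near the floor. They had too few reads for the chi-square test, so their differences between tumours were not tested.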

Other observations

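The tests of the gut and liver markers apart, the explanations below were set out before their results were seen, and the patterns themselves were found in these data. Single genes also differed between tumours. LRRC15, a marker of activated fibroblasts, was at 1164 RPM in UPS 5 and 179.8 RPM in UPS 4, against 0.225 to 7.21 RPM in the other 4. The imprinted non-coding genes differed widely: H19 ranged from 149.5 RPM in UPS 1 to 22964 RPM in UPS 2, and MEG3 from 4.04 RPM in UPS 3 to 3701 RPM in UPS 5. CDKN2A, the gene of the cell cycle inhibitor p16, was at 21.5 RPM in UPS 5 and 38.8 RPM in UPS 6 and at 0.675 RPM or less, no more than 3 reads, in the other 4. The nerve growth factor receptor gene NGFR was at 538.2 RPM and the hedgehog target GLI1 at 71.8 RPM in UPS 3, with at most 145.7 and 15.3 RPM elsewhere. The collagenase gene MMP1 was at 1046 RPM in UPS 1 and at 6.53 to 78.4 RPM in the rest. The testis antigen PRAME was at 48.6 RPM in UPS 6 and 16.2 RPM in UPS 4 and at 0.674 RPM or less elsewhere.

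Erythroid membrane and globin genes did not go together. SLC4A1, the anion exchanger of red cells, was at 1500 to 4168 RPM in all 6 tumours and was highest in UPS 3, where HBA2 was lowest at 28.1 RPM. In UPS 4 the osteoblast transcription factor gene RUNX2 was at 15.5 RPM, against 4.69 RPM or less elsewhere.

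Of the 20 skeletal muscle genes, 16 were highest in UPS 5 and next in UPS 4, among them all 14 with a mean of at least 10 RPM; the marker sets below were chosen after that was seen in the list scores. If muscle fibres in the sampled tissue were the source, further adult fibre genes were to follow the same order of tumours, and 5 of 12 did (41.7%, against 3.33% by chance). If a programme of developing muscle were the source, myogenic and developmental genes were to follow it, and 2 of 5 did: MYOD1 at 69.6 and 7.21 RPM and MYH3 at 22.1 and 16.8 RPM in UPS 5 and UPS 4, while CDH15 was highest in UPS 4 at 196.1 RPM. MYOD1 was also a member of the skeletal muscle list that showed the pattern, so this set was not independent of it. Genes with a mean under 1 RPM were not counted, so a near absence could not tell against either source. In UPS 5 the myogenic and developmental genes not counted stood at 0 to 1.76 RPM. The adult fibre genes not counted stood there at 0.195 to 3.91 RPM. Most genes of both sets were highest in UPS 5. Most adult fibre genes that missed the order did so because UPS 4 was not next, some of them at low values. Both shares lay between the bounds set beforehand, so muscle tissue and a muscle programme of the tumour cells cannot be told apart, and no biological explanation by sample group was tested, because the labels give 1 group.

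Some transcripts that mesenchymal tissue holds in abundance had low values, such as VIM at 64.3 RPM, COL3A1 at 103.9 RPM, B2M at 116.5 RPM and EEF1A1 at 175.9 RPM, beside ACTB at 32247 RPM. COL1A2, whose product joins that of COL1A1 in type I collagen, averaged 444.3 RPM against 5366 RPM for COL1A1, and their transcript ends had a GC content of 33.6% and 63.8%. Not every contrast went with GC content: the ends of ACTB and B2M had 43% and 40.8%. The end of RNF168, at 28124 RPM, had 33%. Across the 400 list members with a GC value the mean level went with GC content (Spearman's rho = 0.43, across genes, which are not independent replicates), as it did across 12165 genes in each tumour (0.35 to 0.43). A loss of AT-rich fragments in library making or mapping may therefore account for part of the differences between lists, and levels of different genes within a tumour are less firm than levels of 1 gene between tumours. True differences in abundance that go with GC content stay open, since no other measure of these transcripts was used here.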
